A study of Homo sapiens with 12 samples.

How the data were processed

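The deposited values were gene counts and FPKM for 58735 genes in each of the 12 libraries, all of whose identifiers had the same start and end in GENCODE release 29. The gene counts were made by the authors from reads cleaned with fastp and aligned with HISAT2 2.2.1 to hg38, as named in the submitters' processing notes; the counting tool, the annotation, the strand setting and the handling of rRNA or poly(A) selection are not given in the sources used here. Per the labels, total RNA was extracted with TRIzol and sequenced after a standard Illumina library preparation. The FPKM deposited by the authors equalled values computed from the counts up to 1 factor per library (0.9334 to 1.0879, largest relative departure 1.1e-08), so they were used only in alternatives.

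Gene counts deposited by the authors were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed by filterByExpr with its defaults, which kept 18560 genes and 99.88 to 99.93% of the counts. Libraries were scaled by TMM, with factors from 0.922 to 1.069. A single quasi-likelihood fit of the 12 libraries with 4 group means gave 4 pairwise contrasts and the interaction, each adjusted by Benjamini-Hochberg over its genes and called at an adjusted p under 0.05. The SE of a log2 fold change is its absolute value divided by the square root of F. Gene lists were compiled from general knowledge and tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with the adjustment over 32 lists, and again with an estimated correlation. The groups, contrasts and alternatives were chosen before the data were examined, apart from GC correction, the within-group axis and the tests described as chosen later.

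Genes outside the lists were named when they had a mean of at least 50 counts and ranked among the 8 largest log2 fold changes in a direction (6 for the interaction), and list members by the smallest p. Single values of a few genes are not reported here. CPM of 3 counts was 0.0854 to 0.116, which bounds the precision of low values. The GC alternative removed, for each library, a spline of 5 degrees of freedom on transcript GC content (18552 genes). Other alternatives were other scalings, filters, DESeq2 1.42.0, voom, FPKM with a linear model, thresholds, omission of each library and list tests with fry.

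The pipeline was tested on simulated data. For TGFB against con it called 14, 60, 92 and 100% of 50 genes changed by log2 values of 0.25, 0.5, 1 and 2, with 4 false calls in 17947 genes, and for the interaction 4, 30, 74 and 94%, with 7 false calls in 17999 genes. With a GC trend added to the simulated counts there were 2078 false calls without the GC offset and 5 with it, among 17943 genes. In the simulated lists, 5 of 5 raised ones were called, and 1 of 10 unchanged ones. Simulated genes varied independently of one another. The list p-values, which depend on the correlation between genes, were therefore not tested in this respect.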

Results

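RNA sequencing measured gene expression in LX-2 cells, an established human hepatic stellate cell line that is widely used as a culture model of liver fibrosis. The 12 libraries form 4 groups of 3: untreated cells (con), cells given TGF-β1 (TGFB), cells transfected with siRNA against NAT10 (SiNAT10), and cells given the siRNA and then TGF-β1 (SiNAT10_TGFB). TGF-β1, the main cytokine that turns stellate cells into matrix-producing myofibroblasts, was used at 5 ng/ml for 24 h. The siRNA was delivered with Lipofectamine 48 h before TGF-β1. How long after transfection the SiNAT10 cells without TGF-β1 were harvested is not given in the sources used here. NAT10 encodes an RNA cytidine acetyltransferase of the nucleolus that acts on 18S rRNA, tRNA and mRNA. The labels name no group with a control siRNA. As labelled, the siRNA comparisons contain the effects of transfection and of NAT10 knockdown together. Cells whose labels name no siRNA are called untransfected here. Total counts per library ran from 25877008 (SiNAT10_TGFB replicate 2) to 35132582 (TGFB replicate 1), and the siRNA libraries, at up to 28311434, were shallower than the others, at 29797990 or more. In the principal components of the 18560 genes tested, PC1 (50.2% of variance) separated the siRNA groups from the others, and PC2 (16.2%) separated the TGF-β1 groups from the rest. Levels are CPM with TMM scaling, as mean ± SD with n = 3. Log2 fold changes carry a standard error (SE), p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, and those of gene lists from camera with the same adjustment over 32 lists. The labels call the libraries of a group biological replicates without naming separate cultures, so the p-values measure the spread between these samples.

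NAT10 (ENSG00000135372; hg38 chromosome 11, 34105602 to 34147670) stood at 62.9, 68.8 and 69.9 CPM in the con libraries and at 67.8, 65.6 and 67.5 CPM in the TGFB libraries. It stood at 19.5, 18.5 and 17.9 CPM in the SiNAT10 libraries and at 19.2, 15.8 and 20.7 CPM in the SiNAT10_TGFB libraries. The siRNA thus came with a level 72.3% lower, a log2 fold change of −1.85 against con (SE 0.087) and of −1.85 against TGFB (SE 0.088). TGF-β1 left no detectable change of NAT10, with an adjusted p of 0.984 without siRNA and 0.988 with it. All 12 libraries matched their labels in this respect.

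The TGFB and con groups address what TGF-β1 does in cells that were not transfected. FN1, fibronectin (ENSG00000115414; chromosome 2, 215360440 to 215436172), rose from 3171 ± 162 to 15362 ± 620 CPM, a log2 fold change of 2.28 (SE 0.058, adjusted p = 1.25e-18). CCN2, the connective tissue growth factor that the files list as CTGF (ENSG00000118523; chromosome 6, 131948176 to 131951373), rose from 221 ± 11.7 to 1188 ± 39.2 CPM, a log2 fold change of 2.43 (SE 0.064). COL1A1, the alpha-1 chain of type I collagen (ENSG00000108821; chromosome 17, 50183289 to 50201632), rose from 3041 ± 124 to 7550 ± 393 CPM, a log2 fold change of 1.31 (SE 0.075). COL3A1, type III collagen (ENSG00000168542; chromosome 2, 188974320 to 189012746), rose from 62.7 ± 4.37 to 200.25 ± 5.85 CPM, a log2 fold change of 1.68 (SE 0.097). TGFB1, the cytokine's own gene, rose by a log2 fold change of 1.42 (SE 0.078), from 193 ± 10.4 to 516 ± 30.3 CPM. COL1A2 rose too, by 2.05 (SE 0.24), but at 1.41 ± 0.225 CPM in con and 5.82 ± 1.14 CPM in TGFB it was scarcely expressed. ACTA2, smooth muscle actin and the usual marker of stellate cell activation, was low in every group. Its 3.27 ± 0.464 and 4.21 ± 0.237 CPM did not differ past the threshold (adjusted p = 0.203). Of its exon bases 30.1% overlap an antisense gene, so its counts are less certain. TIMP1, an inhibitor of matrix proteases, stood at 169 ± 12.1 and 186 ± 9.88 CPM (adjusted p = 0.126), and passed only with the axis of variation within groups as a covariate (0.14, adjusted p = 0.0157).

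**Figure D1:**
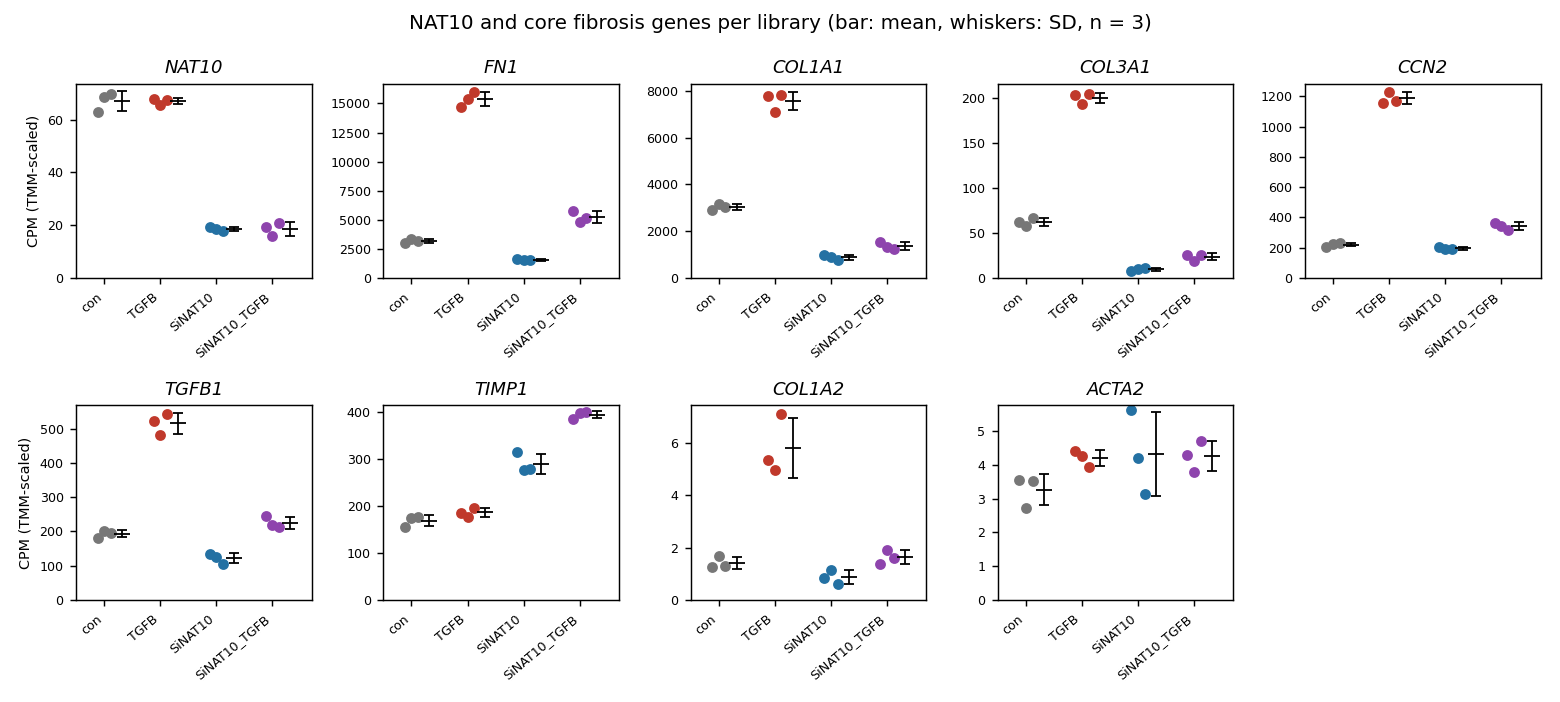
CPM (TMM-scaled, linear axes from 0) of NAT10 and 8 core fibrosis genes in each of the 12 libraries, with points for single libraries and bars for the mean ± SD of the 3 libraries of a group. NAT10 lay between 15.8 and 20.7 CPM in the siRNA libraries against 62.9 to 69.9 CPM in the others, and FN1 went from 3171 to 15362 CPM with TGF-β1 in untransfected cells and from 1565 to 5249 CPM after siRNA.

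Of the 18560 genes tested, 2213 were higher and 2259 lower in TGFB than in con, 601 and 399 of them by a log2 fold change of at least 1. With scaling to library size alone 1410 were higher and 4623 lower, so 23.4% of the calls were higher in place of 49.5%. That scaling moved the median log2 fold change of all genes by −0.14, and the values here are relative to TMM scaling. Among the 9 core fibrosis genes 7 rose and none fell (8 and 0 when adjusted over the list alone; list adjusted p = 6.4e-11). Of 34 direct TGF-β/SMAD response genes, 27 rose and 2 fell (29 and 2 adjusted over the list alone), with a median of 1.47 and a list adjusted p of 5.7e-24. PMEPA1, a membrane protein that restrains TGF-β signalling, rose by 4.91 (SE 0.081), TGFBI, a secreted matrix protein, by 2.86 (SE 0.053), and ADAM19, a membrane metalloprotease, by 2.33 (SE 0.058). Of 35 collagens and collagen maturation genes, 25 rose and 2 fell (26 and 2 adjusted over the list alone, list adjusted p = 1.5e-13). LOX, the collagen cross-linking oxidase (ENSG00000113083; chromosome 5, 122063195 to 122078360), rose by 2.41 (SE 0.072) and the basement membrane collagen gene COL4A1 by 2.03 (SE 0.059). Of 23 contractile and cytoskeletal genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone, list adjusted p = 2.75e-09). TAGLN, transgelin, of whose exon bases 11.4% overlap an antisense gene, rose by 2.16 (SE 0.064) and CALD1, caldesmon, by 1.42 (SE 0.062). Of 25 other matrix glycoproteins, 17 rose and 4 fell (18 and 4 adjusted over the list alone), including THBS1, thrombospondin 1, at 2.42 (SE 0.056). The glycoprotein list had an adjusted p of 1.55e-09, and an adjusted p = 0.11 with an estimated correlation. Of 14 integrins, 9 rose and 2 fell (9 and 2 adjusted over the list alone, list adjusted p = 7.54e-05), including ITGA5, a fibronectin receptor subunit, by 1.16 (SE 0.048). Among 23 matrix proteases and inhibitors, 11 rose and 5 fell (11 and 5 adjusted over the list alone, list adjusted p = 0.00211, and adjusted p = 0.151 with an estimated correlation). The gelatinase gene MMP2 rose by 3.22 (SE 0.083) while the collagenase gene MMP1 fell by 1.09 (SE 0.071).

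Outside the matrix lists, TGF-β1 came with higher counts of secretory pathway and sterol genes and lower counts of interferon response and mitosis genes. Of 22 ER chaperone and unfolded protein response genes, 15 rose and none fell (18 and 0 adjusted over the list alone, list adjusted p = 3.07e-08), with HSPA5, the chaperone BiP, up by 0.46 (SE 0.045). Of 25 cholesterol synthesis genes, 17 rose and 3 fell (20 and 3 adjusted over the list alone, list adjusted p = 1.24e-06), with SQLE, squalene epoxidase, up by 0.82 (SE 0.063). Of 39 type I interferon response genes, 22 fell and 1 rose (25 and 1 adjusted over the list alone), with a median of −0.38 and a list adjusted p of 3.07e-08. IFIT1, an antiviral RNA-binding protein, fell by 0.7 (SE 0.11) and IFIT2 fell by 0.5 (SE 0.064). Of 34 mitosis genes, 19 fell and none rose (0 up and 23 down adjusted over the list alone, list adjusted p = 3.41e-06, and adjusted p = 0.152 with an estimated correlation), including ANLN, a cytokinesis scaffold, at −0.53 (SE 0.058). The 27 NF-kB and inflammatory genes split, with 8 higher and 11 lower (9 and 11 adjusted over the list alone, list adjusted p = 0.382). IL6 and LIF, cytokines of one family, rose by 2.4 (SE 0.097) and 2.1 (SE 0.091). The adhesion molecule VCAM1 fell by 2.21 (SE 0.21) and the chemokine CXCL1 fell by 1.12 (SE 0.087). Of 19 NRF2 and ferroptosis defence genes, 8 fell and 2 rose (9 and 2 adjusted over the list alone, list adjusted p = 0.0223, and adjusted p = 0.189 with an estimated correlation), with the thioredoxin reductase TXNRD1 at −1.03 (SE 0.055). This list was not called with protein-coding genes only (adjusted p = 0.0514) or with the GC trend removed (adjusted p = 0.0509). Among the 8 largest increases of well-counted genes were, beside PMEPA1, KANK4 at 6.93 (SE 0.55), the transcription factor genes FOXS1 at 5.88 (SE 0.38), PKNOX2 at 5.34 (SE 0.45) and EGR2 at 4.45 (SE 0.28), the matrix gene POSTN at 4.25 (SE 0.6) and the Wnt ligand gene WNT7A at 4.05 (SE 0.22). SERPINB2, which encodes PAI-2 and shares 19.9% of its exon bases with a neighbour on the same strand, stood at −3.79 (SE 0.094), and PTX3, a soluble pattern recognition protein, at −2.44 (SE 0.074).

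The SiNAT10_TGFB and TGFB groups address what the siRNA does under TGF-β1. COL1A1 fell from 7550 ± 393 to 1364 ± 165 CPM, a log2 fold change of −2.47 (SE 0.078, adjusted p = 3.44e-17), and COL3A1 fell from 200.25 ± 5.85 to 23.9 ± 3.84 CPM, a log2 fold change of −3.06 (SE 0.1). FN1 fell from 15362 ± 620 to 5249 ± 484 CPM, by −1.55 (SE 0.057), and CCN2 from 1188 ± 39.2 to 342 ± 25.9 CPM, by −1.79 (SE 0.062). TGFB1 fell from 516 ± 30.3 to 226 ± 17.5 CPM, by −1.19 (SE 0.077). COL1A2 was lower as well, at 1.63 ± 0.268 CPM and −1.83 (SE 0.24). TIMP1 went the other way, from 186 ± 9.88 to 395 ± 7.71 CPM, by 1.08 (SE 0.065). ACTA2 did not differ past the threshold, at 4.27 ± 0.455 CPM with siRNA (log2 fold change 0.02, adjusted p = 0.935).

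In this comparison 4886 genes were higher and 4971 lower, 1328 and 1679 of them by at least 1 on the log2 scale. With scaling to library size alone 61.3% of the calls were higher in place of 49.6%, and the median of all genes moved by 0.13. Of the 35 collagen and collagen maturation genes, 25 fell and 3 rose (25 and 3 adjusted over the list alone), with a median of −1.03 (list adjusted p = 4.05e-08). LOX fell by 2.43 (SE 0.072), and COL4A2 and COL5A1 fell by 1.71 (SE 0.051) and by 1.8 (SE 0.061). Of the 23 contractile genes 19 fell and 1 rose (19 and 1 adjusted over the list alone, list adjusted p = 4.05e-08), with TAGLN at −2.09 (SE 0.064) and MYL9, a myosin light chain, at −1.9 (SE 0.057). Of the 25 other matrix glycoproteins, 20 fell and 2 rose (20 and 2 adjusted over the list alone, list adjusted p = 5.51e-07, and adjusted p = 0.141 with an estimated correlation), with THBS2 at −2.04 (SE 0.069). The core fibrosis genes, with 7 lower and 1 higher (7 and 1 adjusted over the list alone), had a list adjusted p of 0.00065, and an adjusted p = 0.12 with an estimated correlation. Of the 34 direct TGF-β/SMAD response genes 18 fell and 4 rose (18 and 4 adjusted over the list alone, list adjusted p = 0.00165, and adjusted p = 0.14 with an estimated correlation), with the SMAD-induced regulator gene ID3 at −2.11 (SE 0.092). Of 14 TGF-β ligand, receptor and SMAD genes 4 rose and 4 fell (4 and 4 adjusted over the list alone, list adjusted p = 0.98). TGFB2, the gene of a second TGF-β ligand, fell by 3.44 (SE 0.11), while TGFBR2, the type II receptor, rose by 1.4 (SE 0.055). TGFB2 shares 26.6% of its exon bases with an overlapping gene, so its value is less certain.

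The siRNA under TGF-β1 also came with higher inflammatory, interferon and p53 target genes and lower mitosis genes. Of the 27 NF-kB and inflammatory genes, 23 rose and 1 fell (23 and 2 adjusted over the list alone), with a median of 1.67 (list adjusted p = 2.45e-11). CSF3, the granulocyte colony-stimulating factor (ENSG00000108342; chromosome 17, 40015361 to 40017813), rose by 6.86 (SE 0.22), IL1A by 4.16 (SE 0.12) and IL1B by 3.63 (SE 0.065), both encoding interleukin-1 cytokines. Of the 39 interferon response genes, 35 rose and 1 fell (35 and 1 adjusted over the list alone), with a median of 1.3 (list adjusted p = 1.2e-13). IFIT2 (ENSG00000119922; chromosome 10, 89283694 to 89309276) rose by 2.79 (SE 0.066) and RSAD2, the antiviral enzyme viperin, by 3.05 (SE 0.094). Of 32 p53 target genes, 23 rose and 6 fell (23 and 6 adjusted over the list alone, list adjusted p = 6.42e-05), with the cell cycle inhibitor CDKN1A at 1.57 (SE 0.062) and the stress cytokine GDF15 at 4.2 (SE 0.3). Of the 34 mitosis genes, 30 fell and none rose (30 and 0 adjusted over the list alone), with a median of −0.79 (list adjusted p = 5.4e-13), among them CCNA2, cyclin A2, at −2.43 (SE 0.073) and MKI67, the proliferation antigen Ki-67, at −1.23 (SE 0.056). Of 29 replication-dependent histone genes, 17 rose and 1 fell (17 and 2 adjusted over the list alone, list adjusted p = 2e-04). Transcripts of these histone genes largely lack poly(A) tails, so their counts depend on the library preparation. Of 19 NRF2 and ferroptosis defence genes, 12 rose and 2 fell (12 and 2 adjusted over the list alone, list adjusted p = 0.000366, and adjusted p = 0.078 with an estimated correlation), with HMOX1, heme oxygenase 1, at 2.46 (SE 0.092). Of 14 fatty acid synthesis genes, 11 fell and 1 rose (12 and 1 adjusted over the list alone, list adjusted p = 2e-04, and adjusted p = 0.063 with an estimated correlation), with FASN, fatty acid synthase, at −1.69 (SE 0.11). Of 27 ATF4 and amino acid response genes, 17 rose and 6 fell (17 and 6 adjusted over the list alone, list adjusted p = 0.00934, and adjusted p = 0.129 with an estimated correlation), although SLC7A5, the large neutral amino acid transporter, fell by 3.04 (SE 0.092). MMP1 (ENSG00000196611; chromosome 11, 102789920 to 102798160) rose by 3 (SE 0.072), and the chemokine gene CXCL12 stood at −3.65 (SE 0.12).

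Across well-counted genes, the log2 fold change of this comparison fell with transcript GC content, with a Spearman correlation of −0.36. The median went from 0.18 for genes under 38% GC to −0.54 for genes over 62%. With the GC trend of each library removed, 8312 of the 9857 calls kept their direction and threshold, and the 17 gene lists called here were called again. Collagens and contractile genes remained lower (adjusted p = 1.38e-05 and 2.66e-08), and interferon and inflammatory genes remained higher (adjusted p = 2.96e-13 and 7.05e-12). The collagen median shrank from −1.03 to −0.69 and the contractile one from −0.8 to −0.71. That of the core fibrosis genes went from −1.55 to −1.7.

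The SiNAT10 and con groups address the siRNA without added TGF-β1. COL3A1 fell from 62.7 ± 4.37 to 9.71 ± 1.7 CPM, a log2 fold change of −2.69 (SE 0.11, adjusted p = 5.46e-15), COL1A1 from 3041 ± 124 to 880 ± 101 CPM, by −1.79 (SE 0.076), and FN1 from 3171 ± 162 to 1565 ± 73.3 CPM, by −1.02 (SE 0.056). TGFB1 fell to 122 ± 15.1 CPM, by a log2 fold change of −0.66. TIMP1 rose to 291 ± 21.3 CPM (0.78, SE 0.065). CCN2, at 196 ± 9.96 CPM, was lower by −0.17 (SE 0.061). This CCN2 call was lost, at −0.15 to −0.16, without con replicate 2, con replicate 3, SiNAT10 replicate 2 or SiNAT10 replicate 3. It was also lost with scaling to library size alone (−0.12) or to the upper quartile (−0.14), and with FPKM, a pseudocount of 1 and no filter (−0.17, adjusted p = 0.0977). COL1A2, at 0.858 ± 0.269 CPM, was lower by −0.71 (SE 0.28), and its call was lost without con replicate 2 (−0.58), SiNAT10 replicate 1 (−0.68) or SiNAT10 replicate 3 (−0.52). COL1A2 was not called either with scaling to library size alone (−0.65), no count filter (−0.74), voom (−0.73), only the 2 groups fitted (−0.71, adjusted p = 0.0898) or FPKM with a pseudocount of 1 and no filter (−0.06). ACTA2, at 4.33 ± 1.24 CPM, did not pass the threshold (0.4, adjusted p = 0.0912) but did without SiNAT10 replicate 3 (0.59) and with the GC trend removed (0.45), and it stood at 0.17 without SiNAT10 replicate 1.

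The siRNA without TGF-β1 raised 4900 genes and lowered 4908, by at least 1 on the log2 scale for 1345 and 1532. The directions were largely those of the siRNA under TGF-β1. In both siRNA comparisons 3801 genes were higher and 3923 lower, and 72 went opposite ways, where independent lists would share 1290, 1315 and 2604. Across genes the log2 fold changes had a Pearson r of 0.77 (Spearman rho 0.77), with no library in common and with genes that are not independent replicates. With no count filter r was 0.3. Of the 35 collagen genes, 23 fell and 5 rose (24 and 5 adjusted over the list alone, list adjusted p = 1.89e-05, and adjusted p = 0.0546 with an estimated correlation), including COL7A1, the anchoring fibril collagen, at −2.65 (SE 0.091). Of the 23 contractile genes 17 fell and none rose (17 and 1 adjusted over the list alone, list adjusted p = 1.65e-06), with the smooth muscle actin gene ACTG2 at −2.46 (SE 0.094). The core fibrosis genes as a list were not called, with 6 lower and 2 higher (6 and 2 adjusted over the list alone, list adjusted p = 0.119), but were with no count filter (adjusted p = 0.0118) and with FPKM, a pseudocount of 1 and no filter (adjusted p = 0.0362). The direct TGF-β/SMAD response genes were not called either, with 13 higher and 13 lower (13 and 13 adjusted over the list alone, list adjusted p = 0.906). The transcription factor genes BHLHE40 and JUNB rose by 1.05 (SE 0.054) and 1.31 (SE 0.085; 14.2% of JUNB exon bases overlap an antisense gene), while ID1 fell by 1.5 (SE 0.097) and SMAD6, an inhibitory SMAD, fell by 2.84 (SE 0.2).

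The NF-kB and inflammatory genes, 23 higher and 1 lower of 27 (23 and 2 adjusted over the list alone), had a median of 1.72 (list adjusted p = 3.23e-12). CSF3 rose by 6.34 (SE 0.2), IL1A by 4.09 (SE 0.12) and the neutrophil chemokine CXCL5 by 2.95 (SE 0.11). Of the 39 interferon response genes, 29 rose and none fell (31 and 0 adjusted over the list alone, list adjusted p = 1.08e-09), with the ubiquitin-like protein gene ISG15 at 1.65 (SE 0.076) and IFIT2 at 2.12 (SE 0.064). Of the 25 immediate early genes, 20 rose and 1 fell (20 and 1 adjusted over the list alone, list adjusted p = 4.84e-08), with DUSP1, a MAP kinase phosphatase, at 1.84 (SE 0.069) and the transcription factor KLF4 at 1.99 (SE 0.087). The mitosis genes, 32 lower and none higher of 34 (32 and 0 adjusted over the list alone, list adjusted p = 6.17e-14), included CCNA2 at −2.24 (SE 0.072) and the mitotic kinase PLK1, with 12.5% of exon bases under an antisense gene, at −1.74 (SE 0.077). Of 32 p53 target genes, 25 rose and 5 fell (25 and 5 adjusted over the list alone, list adjusted p = 1.44e-05), with CDKN1A at 1.76 (SE 0.062) and PMAIP1, which encodes the pro-apoptotic protein NOXA, at 1.33 (SE 0.083). Of 14 fatty acid synthesis genes, 11 fell and none rose (11 and 0 adjusted over the list alone, list adjusted p = 3.85e-05). Of 25 cholesterol synthesis genes, 17 fell and 1 rose (17 and 1 adjusted over the list alone, list adjusted p = 6.07e-05, and adjusted p = 0.0546 with an estimated correlation). The fatty acid desaturase SCD stood at −1.11 (SE 0.064). Of 77 cytosolic ribosomal protein genes, 60 rose and 2 fell (61 and 2 adjusted over the list alone, median 0.31, list adjusted p = 2.59e-08, and adjusted p = 0.433 with an estimated correlation). MMP1 and MMP3, both matrix metalloproteases, rose by 3.4 (SE 0.071) and 5.04 (SE 0.4). The bHLH factor gene ATOH8 and CXCL12 stood at −4.65 (SE 0.31) and −3.62 (SE 0.13). The GC trend was present here too, with a Spearman correlation of −0.33 and medians from 0.18 under 38% GC to −0.47 over 62%. With the trend removed, 8418 of the 9808 gene calls and all 18 list calls were kept, including those of the mitosis genes (adjusted p = 5.91e-18), interferon response genes (adjusted p = 5.79e-09) and collagens (adjusted p = 0.00168). The medians of the collagens and core fibrosis genes shrank from −0.95 to −0.68 and from −0.66 to −0.22. That of the mitosis genes went from −0.84 to −0.91.

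**Figure D2:**
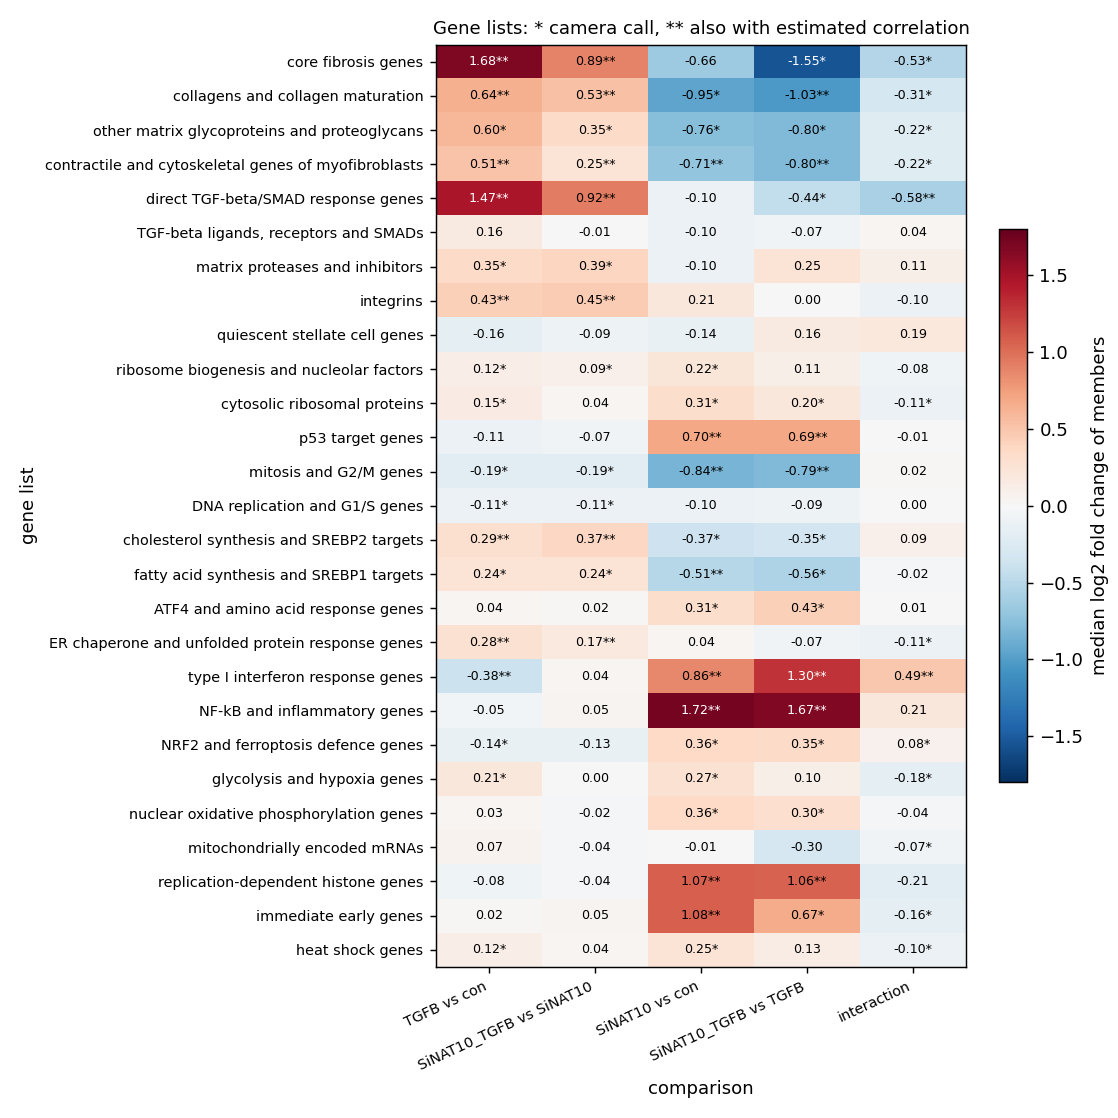
Median log2 fold change of the members of 27 gene lists (vertical axis) in the 5 comparisons (horizontal axis), in colour and as numbers. A star marks an adjusted p under 0.05 in camera with the preset correlation and 2 stars the same with an estimated correlation; the collagen list stood at 0.64 with TGF-β1 alone and at −1.03 for siRNA under TGF-β1, and the interferon list at −0.38 and 1.3.

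The SiNAT10_TGFB and SiNAT10 groups address TGF-β1 in cells that had received the siRNA, although the time after transfection may differ between them. FN1 rose from 1565 ± 73.3 to 5249 ± 484 CPM, a log2 fold change of 1.75 (SE 0.057, adjusted p = 2.65e-16). COL1A1 rose from 880 ± 101 to 1364 ± 165 CPM (0.63, SE 0.074), COL3A1 from 9.71 ± 1.7 to 23.9 ± 3.84 CPM (1.3, SE 0.12) and CCN2 from 196 ± 9.96 to 342 ± 25.9 CPM (0.81, SE 0.061). TGFB1 rose by 0.89 (SE 0.078) and TIMP1 by 0.44 (SE 0.064). COL1A2 was higher by 0.92 (SE 0.28), a call lost without SiNAT10 replicate 1 (0.89), SiNAT10 replicate 3 (0.73), SiNAT10_TGFB replicate 2 (0.79) or SiNAT10_TGFB replicate 3 (0.94). The COL1A2 call was also lost with voom (0.94), with only the 2 groups fitted (0.92, adjusted p = 0.122) and with FPKM, a pseudocount of 1 and no filter (0.09). ACTA2 stood at −0.02 (adjusted p = 0.973). In all, 1098 genes were higher and 956 lower, 271 and 138 by at least 1 on the log2 scale. With scaling to library size alone 36.7% of the calls were higher in place of 53.5%. Removal of the GC trend gave 1411 higher and 1591 lower, so 47% of the calls were higher. Of the 34 direct TGF-β/SMAD response genes, 24 rose and 2 fell (25 and 3 adjusted over the list alone), with a median of 0.92 (list adjusted p = 9.93e-24). PMEPA1 (ENSG00000124225; chromosome 20, 57648392 to 57711536) rose by 4.64 (SE 0.083) and TGFBI by 2 (SE 0.051). Of the 35 collagen genes 18 rose and 2 fell (19 and 2 adjusted over the list alone, list adjusted p = 3.15e-11), with COL4A1 at 1.51 (SE 0.059). The contractile genes, 12 higher and 1 lower (15 and 1 adjusted over the list alone, list adjusted p = 2.4e-07), included TAGLN at 1.14 (SE 0.063). Of the 25 cholesterol synthesis genes 15 rose and 1 fell (20 and 2 adjusted over the list alone, list adjusted p = 1.55e-10), with SQLE at 0.83 (SE 0.065). Of 39 interferon response genes 5 rose and 1 fell (9 and 2 adjusted over the list alone, list adjusted p = 0.21). MMP2 rose by 3.39 (SE 0.088), and the Wnt antagonist SFRP1 and the extracellular protein reelin (RELN) stood at −2.35 (SE 0.097) and −2.61 (SE 0.18).

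The interaction term tests whether the TGF-β1 effect itself differed with siRNA. It was negative for CCN2 at −1.62 (SE 0.086, adjusted p = 3.91e-11), COL1A1 at −0.68 (SE 0.1), FN1 at −0.53 (SE 0.079) and TGFB1 at −0.53 (SE 0.11), each rising less after siRNA. It did not pass the threshold for COL1A2 (−1.12, adjusted p = 0.0997), COL3A1 (−0.37, adjusted p = 0.21), TIMP1 (0.3, adjusted p = 0.0682) or ACTA2 (−0.38, adjusted p = 0.566). It did so for COL1A2 without SiNAT10 replicate 3 (−1.32), for COL3A1 without SiNAT10 replicate 1 (−0.51) and for TIMP1 without con replicate 1 or SiNAT10 replicate 1 (0.36), while ACTA2 stood at −0.15 without SiNAT10 replicate 1. The TIMP1 term also passed with scaling to library size alone (0.38), with no count filter (0.32), with DESeq2 (0.3, adjusted p = 0.0371), with the GC trend removed (0.32) and with the axis of variation within groups as a covariate (0.3). With FPKM and a pseudocount of 1, COL3A1 passed at −0.68 (adjusted p = 0.0205). The calls of TGFB1 (−0.53, adjusted p = 0.108) and COL1A1 (−0.68, adjusted p = 0.0579) were lost with FPKM, a pseudocount of 1 and no filter, and that of TGFB1 also with a pseudocount of 0.1 (−0.52, adjusted p = 0.051). Of all genes tested, 360 had a positive and 354 a negative interaction term past the threshold, 64 and 100 by at least 1. With scaling to library size alone 68.9% of the calls were positive in place of 50.4%. Removal of the GC trend raised the counts to 662 positive and 714 negative. Of the 34 direct TGF-β/SMAD response genes, 17 had a lower and 1 a higher TGF-β1 effect with siRNA (19 and 3 adjusted over the list alone), with a median of −0.58 (list adjusted p = 5.28e-13, and adjusted p = 0.0225 with an estimated correlation). BHLHE40 stood at −1.09 (SE 0.075) and TGFBI at −0.87 (SE 0.07). Of the 39 interferon response genes, 16 had a positive term and none a negative one (23 and 0 adjusted over the list alone), with a median of 0.49 (list adjusted p = 5.28e-13, and adjusted p = 0.0225 with an estimated correlation), including OASL at 0.97 (SE 0.11) and IFIT3 at 0.75 (SE 0.096). The core fibrosis genes, with 5 negative terms and no positive one (7 and 1 adjusted over the list alone), had a list adjusted p of 9.77e-07, and an adjusted p = 0.0864 with an estimated correlation. For the collagens, with 11 negative and 2 positive terms (16 and 3 adjusted over the list alone), these were an adjusted p of 8.17e-06 and an adjusted p = 0.1 with an estimated correlation. LOX stood at −1.83 (SE 0.1). IL6 and LIF, which rose with TGF-β1 alone, had terms of −1.92 (SE 0.13) and −1.7 (SE 0.13), and 20.7% of the exon bases of IL6 overlap an antisense gene.

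**Figure D3:**
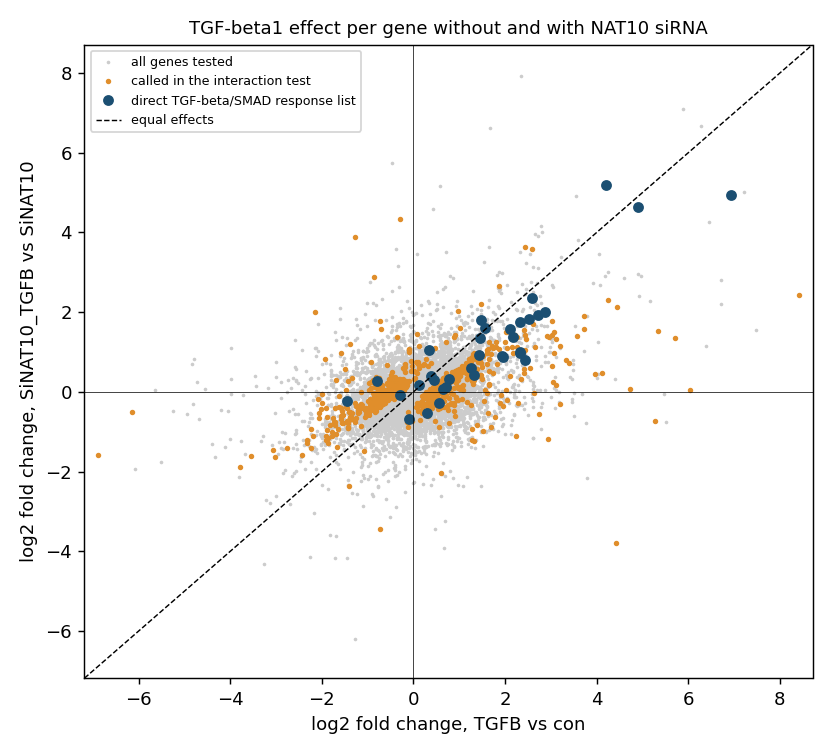
Log2 fold change with TGF-β1 per gene without siRNA (horizontal axis) and with siRNA (vertical axis) for the 18560 genes tested, with the genes called in the interaction test and the direct TGF-β/SMAD response genes marked. The dashed line marks equal effects, and 26 of the 34 direct response genes had the smaller effect with siRNA.

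Across the 18560 genes the TGF-β1 effects without and with siRNA, which share no library, had a Pearson r of 0.43 (Spearman rho 0.4). It was 0.07 with no count filter and 0.73 with genes of at least 50 counts. Of the 2213 genes raised by TGF-β1 in untransfected cells, 855 (38.6%) were also raised after siRNA, and of the 2259 lowered 716 (31.7%) were also lowered. In the interaction test, 325 of the 2213 raised genes had a negative and 15 a positive term, and 309 of the 2259 lowered genes a positive and 2 a negative one, but that test uses the con and TGFB libraries as well. Of the 2213 raised genes, 1114 (50.3%) were lower in SiNAT10_TGFB than in TGFB and 427 were higher, where independent lists would share 593 and 583. Of the 2259 lowered genes, 1015 (44.9%) were higher and 532 lower, where independent lists would share 595 and 605. COL1A1, FN1, CCN2 and LOX were among the raised genes that the siRNA lowered, and IFIT2 and CXCL1 among the lowered genes that it raised. With scaling to library size alone, the opposed genes numbered 668 and 2383 in place of 1114 and 1015, which turns the balance of the directions. These overlaps use the TGFB libraries on both sides, which favours opposite directions. Simulated unchanged groups that shared those libraries gave a mean overlap of 0 genes over 20 sets. They contain no changed genes, so for those the part of the excess that comes from the shared libraries was not measured. The log2 fold changes of the pair had r = −0.3, against −0.49 in the simulated unchanged groups. The simulated r is set by the shared libraries alone, so the 2 values of r cannot be ranked by strength of opposition. The covariance was −0.205 against a simulated covariance of −0.048, a difference of −0.157.

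Counts from ribosomal RNA features moved with the siRNA in every library. The features inside 18S rRNA, minus-strand gene models on chromosome 21 such as FP236383.3 (ENSG00000281181; 8437629 to 8438551, within the 18S copy at 8436876 to 8438744), summed to 3.76 ± 0.964 CPM in con and 7.88 ± 4.61 CPM in TGFB, against 959 ± 315 CPM in SiNAT10 and 1183 ± 229 CPM in SiNAT10_TGFB. That was a geometric mean ratio of 250 for SiNAT10 against con (lowest to highest ratio of single libraries 128 to 423) and of 164 for SiNAT10_TGFB against TGFB (70.1 to 273). The 5.8S rRNA features were 29.4 and 11.6 times as high, and microRNA genes in the spacer of the 45S precursor 31.8 and 16.4 times as high. The mitochondrial rRNA genes were 3.6 and 2.67 times as high, the snoRNA genes 1.81 and 1.59 times, and the replication-dependent histone genes 1.53 and 1.75 times. The rDNA features have identical copies and lie inside or opposite to longer transcripts. The labels state neither the strand setting nor how rRNA was removed, so the source transcript of these counts is uncertain. Of 63 ribosome biogenesis genes 35 rose and 11 fell in SiNAT10 against con (35 and 12 adjusted over the list alone, list adjusted p = 0.00369, and adjusted p = 0.158 with an estimated correlation), with the small subunit processome gene UTP3 at 1.31 (SE 0.069). In SiNAT10_TGFB against TGFB 28 of these ribosome biogenesis genes were higher and 14 lower (29 and 15 adjusted over the list alone), and the list was not called (adjusted p = 0.0575, and adjusted p = 0.324 with an estimated correlation). It was called without TGFB replicate 2 (adjusted p = 0.0433), SiNAT10_TGFB replicate 1 (adjusted p = 0.0426) or SiNAT10_TGFB replicate 2 (adjusted p = 0.0486), and with scaling to library size alone (adjusted p = 0.00591) or the GC trend removed (adjusted p = 0.0462).

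**Figure D4:**
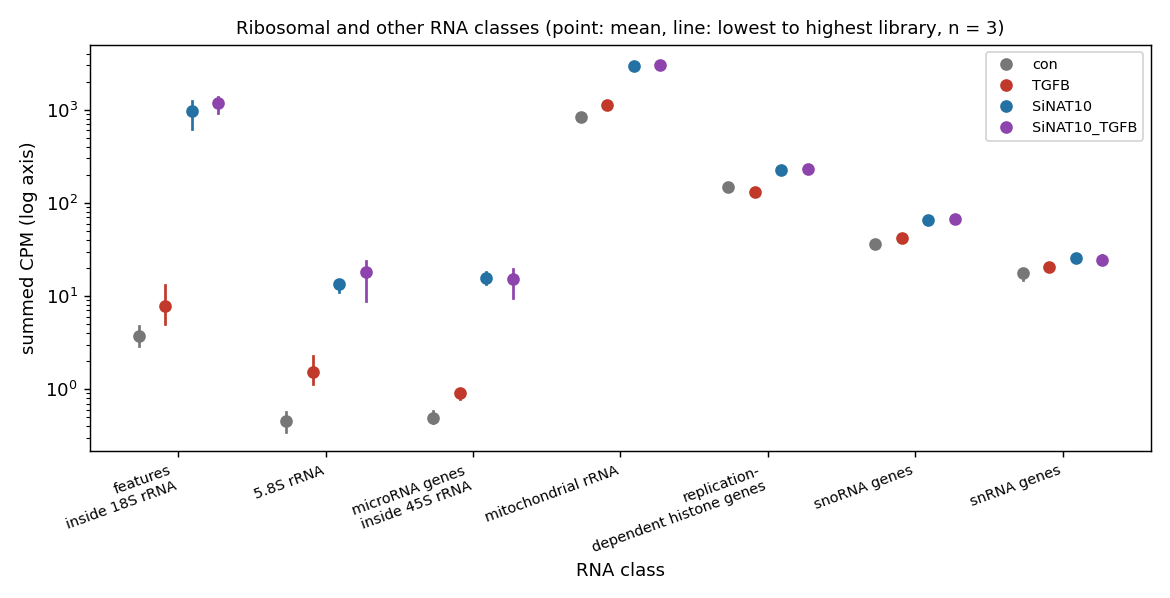
Summed CPM (log axis) of 7 classes of RNA genes in the 4 groups, with points for the mean and lines from the lowest to the highest of 3 libraries. Group means of features inside 18S rRNA lie at 3.76 and 7.88 CPM without siRNA and at 959 and 1183 CPM with it. Group means of snRNA genes stay between 17.7 and 25.7 CPM.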

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

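The splits of the libraries, the scaling test and the test of genes selected on the siRNA arm were set before the results were seen; the tests of GC content, of knockdown against transfection and of the fixed list were chosen after they were seen. The interaction called 360 genes as positive and 354 as negative. COL1A1 (−0.68), FN1 (−0.53), CCN2 (−1.62) and TGFB1 (−0.53) had the smaller TGF-β1 effect with siRNA. Among the largest terms, SERPINB2, which encodes PAI-2, stood at 1.92 (SE 0.12), EPHA4, an ephrin receptor, at 1.7 (SE 0.15), and PARD6B, a cell polarity protein, at 1.73 (SE 0.29). EVI2B and EVI2A, which lie inside an intron of NF1 and share 30.1% and 25.3% of their exon bases with a neighbour on the same strand, stood at 1.92 (SE 0.3) and 1.61 (SE 0.33). KRT14, a keratin, stood at −2.66 (SE 0.47), the potassium channel gene KCNK3 at −2.37 (SE 0.28) and the transcription factor gene EGR2 at −2.31 (SE 0.4). THBS1-IT1, listed as AC037198.1 and lying inside an intron of THBS1, stood at −3.49 (SE 0.46). NPIPA9, listed as AC126755.2 and 65.5% shared with its copies, stood at 2.08 (SE 0.35). BOLA2B, 73.7% shared with its copies, stood at −8.23 (SE 1.9) and was lost without TGFB replicate 1 (−4.09) or SiNAT10 replicate 1 (−3.67). PKNOX2 stood at −3.82 (SE 0.99) and was lost without SiNAT10 replicate 2 (−2.63) or SiNAT10_TGFB replicate 3 (−3.69), and in DESeq2 it had an adjusted p of 0.0818. With FPKM and a pseudocount of 1 the calls of PARD6B (0.34, adjusted p = 0.299), EVI2A (0.33, adjusted p = 0.47) and BOLA2B (−2.45, adjusted p = 0.504) were lost, and without the filter also those of EVI2B (0.63, adjusted p = 0.108) and NPIPA9 (1.06, adjusted p = 0.0528). With a pseudocount of 0.1 those of EVI2A (1.27, adjusted p = 0.0575) and BOLA2B (−3.43) were lost, and BOLA2B was lost with voom too (−3.77).

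In fits of the 6 libraries of a comparison, the real grouping called 5383 genes for TGFB against con, and the highest of the other splits 0. For SiNAT10_TGFB against TGFB these were 10010 and 0, for SiNAT10 against con 9181 and 0, and for SiNAT10_TGFB against SiNAT10 1621 and 1. Lists called were 18 against at most 11, 17 against 13, 18 against 12, and 13 against 10. Groupings that called no gene thus still called up to 13 of 32 lists at the preset correlation. Small list p-values at that correlation therefore do not by themselves mark the real grouping. The real grouping alone reached its count, 1 of 10 each time, and 10 splits are too few for a share under 0.05. For the interaction, 6 of 100 splits within the siRNA arms, the real labels among them, called at least the 714 genes of the real labels, up to 4915, and 11 of 100 called at least its 14 lists, up to 18. By these counts chance was not excluded. For lists, splits that mixed con and TGFB were among those that reached 14, but only with the labels of an arm swapped as well. Mixed splits without such a swap called at most 5 lists. For genes, the splits that reached the count were not draws of chance alone. The 5 that called more genes kept con and TGFB as labelled and swapped labels in the siRNA arm (1814 to 4915 genes), which turns the 2 TGF-β1 effects against each other, 3 with no swap called 358 to 654, and the 91 that mixed con and TGFB called 0 to 3.

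The smaller TGF-β1 effect with siRNA may come in part from the choice of genes. Of genes called with TGF-β1 in untransfected cells, 90.4% lacked a larger effect in the same direction with siRNA. This share includes genes with opposite directions, and selection alone would favour it. Of the 2054 genes called in the siRNA arm, where selection alone would favour the reverse, 56.7% had a larger effect in the same direction without siRNA. This argues against selection as the whole source among these genes. The share fell short of the 60% set beforehand for excluding selection, so a part played by selection stayed open for genes at large. Among the 2054 genes, 155 raised ones had a negative and 63 a positive interaction term. Of the lowered ones, 109 had a positive and 38 a negative term. The list of direct response genes was not chosen on these data. In it 26 of 34 members had the smaller effect with siRNA (76.5%, exact 95% interval 58.8 to 89.3). This argues against selection as the source there, although the members are not independent of one another. The list medians were 1.47 without and 0.92 with siRNA. By total least squares with a free intercept, the slope of the effects with siRNA on those without was 0.86. Such a slope leaves out a shift common to all members, so it cannot be set against the medians as a size of reduction. Scaling did not account for the smaller effect, since the median interaction term of that list stayed at −0.50 or lower under 3 other scalings. Neither did GC content, with −0.55 after removal of the trend. The main value of −0.58 could follow from NAT10 knockdown, from transfection or from a difference in time after transfection, which the groups do not separate.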

How the results depend on the processing

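With scaling to library size alone, TGFB against con had 1410 genes higher and 4623 lower, SiNAT10_TGFB against SiNAT10 had 1510 lower and the interaction 641 positive. Genes raised by TGF-β1 and lower with siRNA numbered 668, and those lowered and higher 2383. This follows from the shift of all genes together. With the log2 limit of 1, the counts were 601 and 399 for TGFB against con, 1328 and 1679 for SiNAT10_TGFB against TGFB, 1345 and 1532 for SiNAT10 against con, 271 and 138 for SiNAT10_TGFB against SiNAT10, and 64 and 100 for the interaction, and the opposed genes were 201 and 165. At an adjusted p under 0.01, 1501 genes were lower in TGFB against con and 540 in SiNAT10_TGFB against SiNAT10, and the interaction had 174 and 209; both settings only tighten the rule.

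The correlation of the TGF-β1 effects was 0.07 with no count filter, 0.56 with FPKM and a pseudocount of 1, 0.54 with only the 2 groups of each comparison fitted, 0.56 with protein-coding genes and 0.73 with genes of at least 50 counts. That of the siRNA effects was 0.3 with no count filter, 0.85 with FPKM and 0.9 with genes of at least 50 counts. With FPKM, a pseudocount of 1 and no filter, SiNAT10_TGFB against SiNAT10 had 627 genes lower, the interaction 190 and 234, and 650 genes were lowered by TGF-β1 and higher with siRNA; the cause was not tested.

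With an estimated correlation, the lists called fell to 8 in TGFB against con, 7 in SiNAT10_TGFB against TGFB, 8 in SiNAT10 against con, 7 in SiNAT10_TGFB against SiNAT10 and 2 in the interaction, 32 of 80 in all. With fry 30 lists were called in SiNAT10_TGFB against TGFB, as fry tests each list by itself.

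With the GC trend removed, 1591 genes were lower in SiNAT10_TGFB against SiNAT10 and the interaction had 662 and 714. TIE1, an endothelial receptor, reversed to 0.09 under TGF-β1 (from −0.3) and to 0.12 without it (from −0.24). With a replicate block added these were 1482, 595, 648, 0.09 and 0.12. With the axis of variation within groups as a covariate, SiNAT10_TGFB against SiNAT10 had 1665 and 1553 and the interaction 849 and 784; the cause was not tested.

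The replicate numbers did not pair, since libraries of the same number had correlations from −0.59 to 0.38; with the block, 544 of 555 named gene calls and 80 of 80 list calls were kept. DESeq2 kept 553 of 554, voom 545 of 555, and the omission of any library at least 540. Scaling to library size alone kept 533 of 555. FPKM with a pseudocount of 1 kept 524 of 545, and 508 of 555 without the filter.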

Other observations

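Markers of hepatocytes, macrophages and lymphocytes were low, while some endothelial and epithelial markers were not. SERPINA1, a hepatocyte product, had a mean of 20.2 CPM as the highest hepatocyte marker, CD14 3.31 CPM among macrophage markers and CD4 3.16 CPM among lymphocyte markers. KRT18, a keratin also seen in cultured mesenchymal cells, reached 304 CPM and FLT1, a VEGF receptor, 179 CPM. TIE1, an endothelial receptor, stood at 126 to 180 CPM over the 12 libraries. The epithelial markers summed to 570 CPM in con and 839 CPM in TGFB, against 607 CPM in SiNAT10 and 601 CPM in SiNAT10_TGFB. VEGFA, which encodes the vascular growth factor, rose by 1.71 (SE 0.076) with TGF-β1 in untransfected cells and by 1.3 (SE 0.076) with siRNA alone. Of 49 nuclear oxidative phosphorylation genes 31 rose and 3 fell in SiNAT10 against con (31 and 3 adjusted over the list alone, list adjusted p = 3.08e-05, and adjusted p = 0.329 with an estimated correlation), with SDHB, a succinate dehydrogenase subunit, at 0.83 (SE 0.087).

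Weaker list calls in the interaction depended on single libraries, and so did the call of the cytosolic ribosomal protein genes. That list had a median of −0.11 (list adjusted p = 0.000161, and adjusted p = 0.641 with an estimated correlation). Without SiNAT10_TGFB replicate 1 it was not called (median −0.04, adjusted p = 0.184). Of 7 cholangiocyte and epithelial markers 3 had a negative and none a positive term (3 and 0 adjusted over the list alone, list adjusted p = 0.0395, and adjusted p = 0.174 with an estimated correlation), with KRT8, a keratin, at −0.54 (SE 0.087). Without con replicate 1, TGFB replicates 2 or 3, SiNAT10 replicates 2 or 3, or SiNAT10_TGFB replicates 1 or 3 this call was lost, at medians from −0.41 to −0.32. Of 19 NRF2 and ferroptosis defence genes 3 had a positive and 0 a negative term (4 and 0 adjusted over the list alone). The NRF2 list had an adjusted p of 0.0395, and of 0.329 with an estimated correlation. Its call was lost without con replicate 3, TGFB replicate 3, SiNAT10 replicates 1 or 3, or SiNAT10_TGFB replicates 2 or 3, at medians from 0.05 to 0.13. Of 25 immediate early genes 7 had a negative and 3 a positive term (10 and 4 adjusted over the list alone, list adjusted p = 0.0244, and adjusted p = 0.329 with an estimated correlation), with DUSP1 at −1.09 (SE 0.095); the call was lost without SiNAT10 replicates 1 or 2 (median −0.12). Of 14 heat shock genes 2 had a negative term (2 and 0 adjusted over the list alone, list adjusted p = 0.0395, and adjusted p = 0.329 with an estimated correlation). That call was lost without any con library, TGFB replicates 1 or 2, SiNAT10 replicate 3, or SiNAT10_TGFB replicates 1 or 3, at medians from −0.11 to −0.07. Of 13 mitochondrial mRNAs 1 had a negative term (3 and 0 adjusted over the list alone, list adjusted p = 0.0433, and adjusted p = 0.482 with an estimated correlation), and the median of −0.07 became 0.01 with scaling to library size alone. The mitochondrial call was lost without con replicates 2 or 3, TGFB replicates 1 or 3, SiNAT10 replicates 1 or 3, or SiNAT10_TGFB replicates 2 or 3, at medians from −0.07 to −0.03. With no count filter the epithelial (−0.3), heat shock (−0.09) and mitochondrial (−0.05) calls were lost as well, and heat shock also with scaling to library size alone (−0.03).

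The tests of the rRNA rise were all chosen after it was seen. The 18S features stood 250 times as high in SiNAT10 as in con. If the siRNA libraries had carried over more RNA without poly(A) tails in general, histone, snRNA and snoRNA genes would have risen about as much. The largest of their ratios was 1.81. The snRNA and snoRNA genes held only 479 to 797 and 1038 to 1935 counts per library. These ratios argue against an equal rise of all such RNA. They cannot decide on carry-over of rRNA in particular, as none of these classes is rRNA. Mitochondrial rRNA was 3.6 times as high, and 2.67 times under TGF-β1. RN7SL2, the RNA of the signal recognition particle, which also lacks a poly(A) tail, was 3.01 times as high (1.24 to 8.19 between single libraries) and under TGF-β1 0.787 times as high (0.321 to 1.4). If the siRNA libraries had carried over more mature rRNA alone, the spacer microRNA genes would have stayed level. But the lowest ratio of these genes between any siRNA library and any other was 9.48. Without siRNA these spacer genes held only 13 to 30 counts per library. Their ratios of 31.8 and 16.4 were below the 250 and 164 of the 18S features. Carry-over of mature and precursor rRNA together was not tested. NAT10 acts in the processing of the 18S precursor, so knockdown could raise precursor counts, and transfection could too. Without a control siRNA group the value of 250 leaves knockdown and transfection open, along with such carry-over.

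The tests of the GC trend were likewise chosen after it was seen. The strongest axis of variation within groups held 42.1% of that variance and its gene loadings had a Spearman correlation of 0.83 with GC content across 10021 genes, so libraries of 1 group differed along the same line. SiNAT10 replicates 1 and 3 lay furthest apart on this axis, at 11.4 and −13.2, against −7.3 to 5.2 in the other groups. A GC bias of the libraries was not the whole cause of the list calls, as 35 of 35 in the siRNA comparisons were kept with the trend removed. Whether bias made the trend itself stayed open: slopes ran from −0.255 to −0.026 log2 per 10% GC with siRNA and from 0.026 to 0.194 without, a gap of 0.052, while libraries within a group differed by up to 0.229.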
